A study of Homo sapiens with 6 samples.

How the data were processed

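The series holds 6 libraries of polyadenylated RNA from human umbilical vein endothelial cells, 2 each with vehicle, 1 µM simvastatin and 10 µM simvastatin for 24 h. Samples were grouped by the treatment in the labels. The doses are those of the labels' treatment protocol, which also gives a final concentration of 10 µg/ml for the diluted drug without saying how it relates to the doses of 1 µM and 10 µM, so the exact concentrations are uncertain. Reads were aligned with STAR, counted with HTSeq and scaled with DESeq2 on the build GRCh38, per the submitters' processing notes. Their versions, the annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. The deposited values are of the kind signal: in each library they list 30512 Ensembl genes with values that are not whole numbers. Every positive value was a whole multiple of a single step per library (100% within 0.1 read, largest distance 0.0571 reads), as read counts divided by 1 size factor per library would give, so whole reads were recovered from them. The depth so recovered was 4410862 and 2370581 reads in vehicle, 5637440 and 9947297 at 1 µM, and 4525577 and 7464439 at 10 µM, and 18692 to 23589 genes had a read. Of the listed genes, 2803 were at 0 in all 6 libraries. Of the identifiers, 24723 were matched to a symbol and 30449 to GENCODE v29, from which the coordinates were taken.

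The design fixed before the data were examined assumed raw counts and edgeR. Because the deposited unit was normalised, the main test was limma (3.58.1, trend and robust empirical Bayes) on log2(value + 2) in R 4.3.3, with genes of at least 10 in at least 2 libraries, 1 mean per group and all 6 libraries in the fit. It had 3 residual degrees of freedom and a median of 38.8 prior degrees of freedom. The 14135 genes tested leave out XIST and Y-linked genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is on the log2(value + 2) scale and understates the change of low genes. The edgeR quasi-likelihood test (4.0.16) with TMM on the recovered reads called 1950 genes at 1 µM, 2499 at 10 µM and 0 between the doses. DESeq2 (1.42.0), limma-voom, other scalings, filters and pseudocounts, a minimum fold, thinned libraries, a GC and length correction and leaving out each library were run as alternatives. Simulated libraries with known changes were used to test the code: for 1 µM against vehicle over 14135 genes, limma recovered 9.0% of 67 genes changed 1.5-fold, 40.3% of 67 changed 2-fold and 83.3% of 66 changed 4-fold, with 3 false calls, and edgeR recovered 9.0%, 40.3% and 86.4%. Far fewer genes were changed in them than were called in the data, so these shares do not give the power of the real comparisons.

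A total of 29 gene lists were fixed with the design. They cover cholesterol synthesis and SREBP2 targets, fatty acid synthesis and SREBP1 targets, LXR targets, the KLF2 or KLF4 program, YAP and TAZ targets, SRF and actin, coagulation, NF-kB targets, interferon response, endothelial identity, angiogenesis, endothelial to mesenchymal transition, BMP and ID genes, S phase, G2 and M phase, p53 targets, the integrated stress response, oxidative stress, hypoxia and glycolysis, immediate early genes, heat shock, apoptosis and vasoactive genes. The other lists hold markers of smooth muscle cells and pericytes, fibroblasts, leukocytes, epithelial and red cells, and lymphatic endothelium. Some genes stand on several lists. Each was tested with camera at a preset correlation of 0.01, on log2 values rather than the voom values first planned, and adjusted over the 29 lists of a comparison. Camera called 5 lists higher and 5 lower at 1 µM, 4 and 4 at 10 µM, and 1 and 4 between the doses. With an estimated correlation, only the G2 and M phase call held, at 1 µM and at 10 µM (1 list in each, and 0 between the doses). That setting also uses only the 3 residual degrees of freedom, so a lost call need not mean correlated members. At 1 µM the estimate exceeded 0.01 for the called KLF2 or KLF4 (0.0861), SRF (0.147), S phase (0.0935) and immediate early lists (0.0731). It was below 0.01 for the called cholesterol (0.00284), YAP and TAZ (-0.00919), identity (-0.0376), vasoactive (-0.0117) and heat shock (-0.0445) lists. For the G2 and M phase list it was -0.000625. The directional fry test, which does not compare a list with other genes, called 12, 11 and 1 lists. Counts of list members are given over all genes tested and adjusted over the list alone.

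Named genes were chosen by a rule set with the design. Per comparison it took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups, up to 4 members with the smallest adjusted p from each list, and in every comparison a fixed set that included HMGCS1, KLF2, KLF4, THBD, NOS3, F3, CCN1 and CCN2. Part of the genes it gave are named, some genes of the fixed set and 1 of the lists are not reported here, and genes outside it are said to be so. The value of a group is the mean ± SD of 2 libraries. The replicate libraries of each group differed by more than sampling noise (chi-square per degree of freedom 5.61 in vehicle, 12.6 at 1 µM and 8.01 at 10 µM), so none was counted as a copy of another. The SE of a log2 fold change is the moderated SE of the limma fit to all 6 libraries, drawn towards the spread of other genes. It can therefore be smaller or larger than the libraries of that gene alone would give. Intervals are 95% intervals from the limma fit. ACTB, ACTG1, HSPA1A, HSPE1 and HSP90AA1 have near-identical copies or pseudogenes, and antisense partners cannot be told apart without a stated strand, so their values are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.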

Results

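Polyadenylated RNA was sequenced from human umbilical vein endothelial cells (HUVEC), primary cells from the inner lining of the umbilical vein, after 24 h with vehicle, 1 µM simvastatin or 10 µM simvastatin. Simvastatin is a statin, a class of drugs that lower cholesterol synthesis, and the question was how the transcriptome responded to each dose. Each of the 3 groups held 2 libraries. The depth recovered from the deposited values was 4410862 and 2370581 reads in the vehicle libraries, 5637440 and 9947297 reads at 1 µM, and 4525577 and 7464439 reads at 10 µM, so that the shallowest library was in the vehicle group. Mitochondrial genes took 19.7% and 17.0% of the reads in vehicle, 25.2% and 19.7% at 1 µM, and 20.4% and 21.5% at 10 µM. Cytosolic ribosomal protein genes took 3.43% to 4.35% and the 20 most abundant genes of a library 20.1% to 27.9%. These shares are given as values without a test. An exact two-sided permutation test of 2 libraries against 2 cannot go below p = 0.33, and no model was fitted to them. Across genes, the log2 values of the 2 libraries of a group correlated at r = 0.956 in vehicle, 0.978 at 1 µM and 0.97 at 10 µM. The first principal component held 49.1% of the variance and placed the vehicle libraries at -37.39 and -58.73, the 1 µM libraries at 19.23 and 19.97 and the 10 µM libraries at 31.65 and 25.28. The second held 18.1% and placed the vehicle libraries apart from each other, at 41.0 and -30.8. The labels do not say whether the libraries of a group came from separate cultures or donors. The limma p-values therefore rest on the spread between these libraries, which may be technical. That spread was moderated by the spread of other genes (3 residual and a median of 38.8 prior degrees of freedom). Camera at the preset correlation sets a list against the other genes, so its p-values reflect the spread across genes rather than between libraries.

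With 1 µM simvastatin, the flow-responsive transcription factors KLF2 and KLF4 rose, and TOP2A and MCM4, genes of dividing cells, fell. The normalised read count of KLF2 rose from 777 ± 1.98 (SD, n = 2 libraries) in vehicle to 2579.7 ± 178 (SD, n = 2), a log2 fold change of 1.73 ± 0.13 (SE), and that of KLF4 from 72.2 ± 12.5 to 315 ± 26.9 (2.10 ± 0.20). PTGDS, which makes prostaglandin D2, rose from 16.5 ± 1.90 to 205 ± 0.984 (3.49 ± 0.25). TOP2A, a DNA topoisomerase of dividing cells, fell from 1012 ± 39.0 to 358 ± 18.4 (-1.49 ± 0.16), and MCM4, a subunit of the replicative helicase, fell from 459.6 ± 27.6 to 90.0 ± 8.64 (-2.33 ± 0.22). ANKRD1, a target of the YAP and TAZ coactivators, fell from 8385 ± 1756 to 2493 ± 387 (-1.74 ± 0.14).

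Over all genes, limma on log2 values called 1925 of 14135 genes at an adjusted p of 0.05 (Benjamini-Hochberg), 1029 higher and 896 lower at 1 µM than in vehicle. Of these, 421 rose and 373 fell by more than 2-fold. Among the named genes with the largest rises were SMTNL2 (4.04 ± 0.42), which was near the counting floor in vehicle at 2.61 ± 0.894, and NPR1, the natriuretic peptide receptor that makes cyclic GMP (3.02 ± 0.39), which was low and uneven in vehicle at 10.1 ± 8.67. The log2 fold change of NPR1 was 3.83 without vehicle replicate 1 and 2.22 without vehicle replicate 2. NPPB, which encodes a natriuretic peptide, fell (-2.93 ± 0.48). The edgeR quasi-likelihood test on the recovered reads called 1950 genes, of which 1861 were among those called by limma. Without 1 µM replicate 1 or replicate 2 the limma count fell to 988 and 924, and against a minimum fold of 1.5 it was 248.

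In the list of the laminar flow and KLF2 or KLF4 program, 14 of 21 genes tested rose and 0 fell at 1 µM (16 and 0 adjusted over the list alone; median log2 fold change 0.91). For the KLF2 or KLF4 list at 1 µM, camera gave an adjusted p of 7.09e-11 (adjusted p = 0.144 with an estimated correlation). Beside KLF2, KLF4 and PTGDS, elastin (ELN) rose by 2.11 ± 0.16 and the angiopoietin receptor TEK by 1.60 ± 0.15 on the log2 scale. NOS3, the endothelial nitric oxide synthase, rose from 942 ± 47.9 to 2105 ± 43.4 (1.16 ± 0.13). Of the 17 genes tested in the prostanoid, nitric oxide and vasoactive list, which also holds PTGDS and NOS3, 10 rose and 3 fell (10 and 4 adjusted over the list alone). For the vasoactive list at 1 µM, camera gave an adjusted p of 0.00286 (adjusted p = 0.151 with an estimated correlation). RAMP2, a partner of the adrenomedullin receptor, rose by 1.98 ± 0.16 and the cyclooxygenase PTGS1 by 1.23 ± 0.15. Among 25 endothelial identity genes, 13 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.48). For the identity list at 1 µM, camera gave an adjusted p of 0.00273 (adjusted p = 0.151 with an estimated correlation). The adhesion molecule PECAM1 rose by 0.70 ± 0.12 and PLVAP, of the fenestral diaphragm, by 1.17 ± 0.21. Without vehicle replicate 1, 8 identity genes rose, the median was 0.44 and the camera adjusted p was 0.0587, in a range of 0.00157 to 0.0587 over 18 settings. Without vehicle replicate 2, 1 µM replicate 1 or 1 µM replicate 2 the identity genes that rose were 7, 6 and 6, and the median was 0.28 with the GC and length trend removed. The vasoactive genes that fell were 1 without vehicle replicate 1, vehicle replicate 2 or 1 µM replicate 1, and 0 without 1 µM replicate 2.

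Of 23 cholesterol synthesis and SREBP2 target genes tested at 1 µM, 10 rose, 0 fell and 13 were not called (12 and 0 adjusted over the list alone; median 0.67). For the cholesterol list at 1 µM, camera gave an adjusted p of 2.87e-05 (adjusted p = 0.144 with an estimated correlation). IDI1, an isomerase of isoprenoid synthesis, rose by 1.20 ± 0.26, MVD by 1.28 ± 0.27 and FDFT1, which makes squalene, by 0.84 ± 0.16. Without 1 µM replicate 1, 6 genes of the list rose. HMGCS1, an early enzyme of the pathway, rose from 48.0 ± 18.9 to 84.6 ± 5.77 (0.84 ± 0.28; limma adjusted p = 0.0376). HMGCS1 lost its call without vehicle replicate 1 (0.45), 1 µM replicate 1 (0.78), 1 µM replicate 2 (0.91), 10 µM replicate 1 (0.84) or 10 µM replicate 2 (0.84), with DESeq2 (adjusted p = 0.13), with no filter on low values (adjusted p = 0.0697), with only the 4 libraries of the comparison (adjusted p = 0.0858) and against the minimum fold. Apart from the minimum fold its adjusted p lay between 0.00334 and 0.316 over 23 settings.

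At 1 µM, all but 1 of the 25 G2 and M phase genes tested fell (24 fell and 0 rose; 0 and 25 rose and fell adjusted over the list alone; median -1.44). For the G2 and M phase list at 1 µM, camera gave an adjusted p of 1.04e-23 (adjusted p = 0.0403 with an estimated correlation). The mitotic kinase AURKB had a log2 fold change of -2.05 ± 0.23 and the spindle factor TPX2 of -1.52 ± 0.17. Of 25 S phase genes, 19 fell and 0 rose (0 and 22 rose and fell adjusted over the list alone; median -1.34). For the S phase list at 1 µM, camera gave an adjusted p of 3.28e-17 (adjusted p = 0.144 with an estimated correlation). E2F1, a transcription factor of S phase entry, had a log2 fold change of -2.01 ± 0.24 and RRM2, a subunit of ribonucleotide reductase, of -1.77 ± 0.24.

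YAP and TAZ, and SRF, are factors that respond to the state of the actin cytoskeleton. Of 21 YAP and TAZ target genes at 1 µM, 10 fell, 1 rose and 10 were not called (1 and 11 rose and fell adjusted over the list alone; median -0.44). For the YAP and TAZ list at 1 µM, camera gave an adjusted p of 0.00168 (adjusted p = 0.151 with an estimated correlation). AXL, a receptor kinase, was among those that fell (-0.84 ± 0.13). CCN2 fell (-0.56 ± 0.14; limma adjusted p = 0.00602), a call lost without vehicle replicate 1 (-0.52) or 1 µM replicate 1 (-0.50), and CCN1 did not pass (-0.32 ± 0.15; limma adjusted p = 0.159). Of 23 SRF and actin genes, 8 fell, 1 rose and 14 were not called (1 and 9 rose and fell adjusted over the list alone; median -0.31). For the SRF and actin list at 1 µM, camera gave an adjusted p of 0.00267 (adjusted p = 0.387 with an estimated correlation). The median was -0.13 over genes with at least 5 CPM, and -0.21 in thinned libraries. Without 1 µM replicate 1, 4 YAP and TAZ targets and 5 SRF genes fell, and without 1 µM replicate 2, 6 and 5 fell. The YAP and TAZ target that rose lost its call without vehicle replicate 1, 1 µM replicate 2 or either 10 µM library, in thinned libraries, without robust estimation, with no filter on low values, with a total without mitochondrial genes and with the GC and length trend removed. Genes that fell included FHL2 (-0.91 ± 0.14), tropomyosin 1 (TPM1, -0.90 ± 0.13) and the actins ACTB (-0.87 ± 0.12) and ACTG1 (-0.76 ± 0.11), which share near-identical sequence with each other and with pseudogenes, so that their values are uncertain.

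Of 20 coagulation and fibrinolysis genes, 7 rose and 2 fell at 1 µM (8 and 4 adjusted over the list alone; camera adjusted p = 0.444). Thrombomodulin (THBD), which turns thrombin towards anticoagulation, rose from 309 ± 14.2 to 709 ± 58.7 (1.19 ± 0.15). VWF, the platelet adhesion protein, rose by 0.78 ± 0.13 and S100A10 by 0.81 ± 0.13. Tissue factor (F3) was too low to be tested, with a largest value of 11.9 in any library. The coagulation genes that fell were 4 without vehicle replicate 1, and 1 without vehicle replicate 2, without 1 µM replicate 2 or with no filter on low values. Of 20 immediate early genes, 10 rose and 1 fell (10 and 3 adjusted over the list alone; median 0.41). For the immediate early list at 1 µM, camera gave an adjusted p of 0.0147 (adjusted p = 0.385 with an estimated correlation). Members that changed included FOSB (2.02 ± 0.15), NR4A2 (2.08 ± 0.18) and JUNB (1.30 ± 0.17). The median of the list was 0.18 with no filter on low values, 0.63 over genes with at least 5 CPM and 0.19 with the GC and length trend removed. The immediate early genes that fell were 0 without vehicle replicate 1 or 1 µM replicate 2, and 2 without vehicle replicate 2 or with the GC and length trend removed. Of 14 heat shock and chaperone genes, 5 fell and 1 rose (1 and 6 rose and fell adjusted over the list alone; median -0.34). For the heat shock list at 1 µM, camera gave an adjusted p of 0.0374 (adjusted p = 0.281 with an estimated correlation). The mitochondrial cochaperonin HSPE1 had a log2 fold change of -1.26 ± 0.16 and HSP90AA1 of -0.85 ± 0.12, while HSPB1 rose by 0.67 ± 0.12. Without 1 µM replicate 1 or replicate 2, 3 heat shock genes fell. The camera call of the heat shock list was lost without vehicle replicate 1 (median -0.10, adjusted p = 0.111), 1 µM replicate 1 (-0.30, adjusted p = 0.0692) or 1 µM replicate 2 (-0.32, adjusted p = 0.06), in a range of 0.0119 to 0.111 over 18 settings.

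Among markers of other cell types at 1 µM, 2 of 7 fibroblast genes rose and 0 fell, 2 of 8 smooth muscle and pericyte genes fell and 0 rose, 1 of 3 leukocyte genes rose, 1 epithelial gene rose and 1 fell of 6, and 0 of 6 lymphatic genes changed. The fibroblast genes that rose were 4 without vehicle replicate 1, and 1 without vehicle replicate 2 or 1 µM replicate 1, and the smooth muscle genes that fell were 0 without vehicle replicate 2, and 1 without 1 µM replicate 1 or replicate 2, without robust estimation or with the GC and length trend removed. The leukocyte gene lost its call when any 1 of the vehicle or 1 µM libraries was left out, in thinned libraries, with no filter on low values, without robust estimation and with a total without mitochondrial genes. The epithelial gene that rose lost its call when vehicle replicate 2 or either 1 µM library was left out and with the GC and length trend removed, where 1 lymphatic gene rose. PI16, on the fibroblast list, rose from 88.8 ± 36.9 to 771 ± 62.8 (3.15 ± 0.20), and KRT7, on the epithelial list, fell from 1957 ± 243 to 476 ± 15.7 (-2.03 ± 0.15). In GRCh38 with GENCODE v29, KLF2 (ENSG00000127528) lies on chromosome 19, 16324817 to 16327874, KLF4 (ENSG00000136826) on chromosome 9, 107484852 to 107490482, PTGDS (ENSG00000107317) on chromosome 9, 136975092 to 136981742, ANKRD1 (ENSG00000148677) on chromosome 10, 90912096 to 90921276, MCM4 (ENSG00000104738) on chromosome 8, 47960185 to 47978160, TOP2A (ENSG00000131747) on chromosome 17, 40388516 to 40417950, PI16 (ENSG00000164530) on chromosome 6, 36948263 to 36964837 and KRT7 (ENSG00000135480) on chromosome 12, 52232520 to 52252186, all annotated as protein coding genes.

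**Figure D1:**
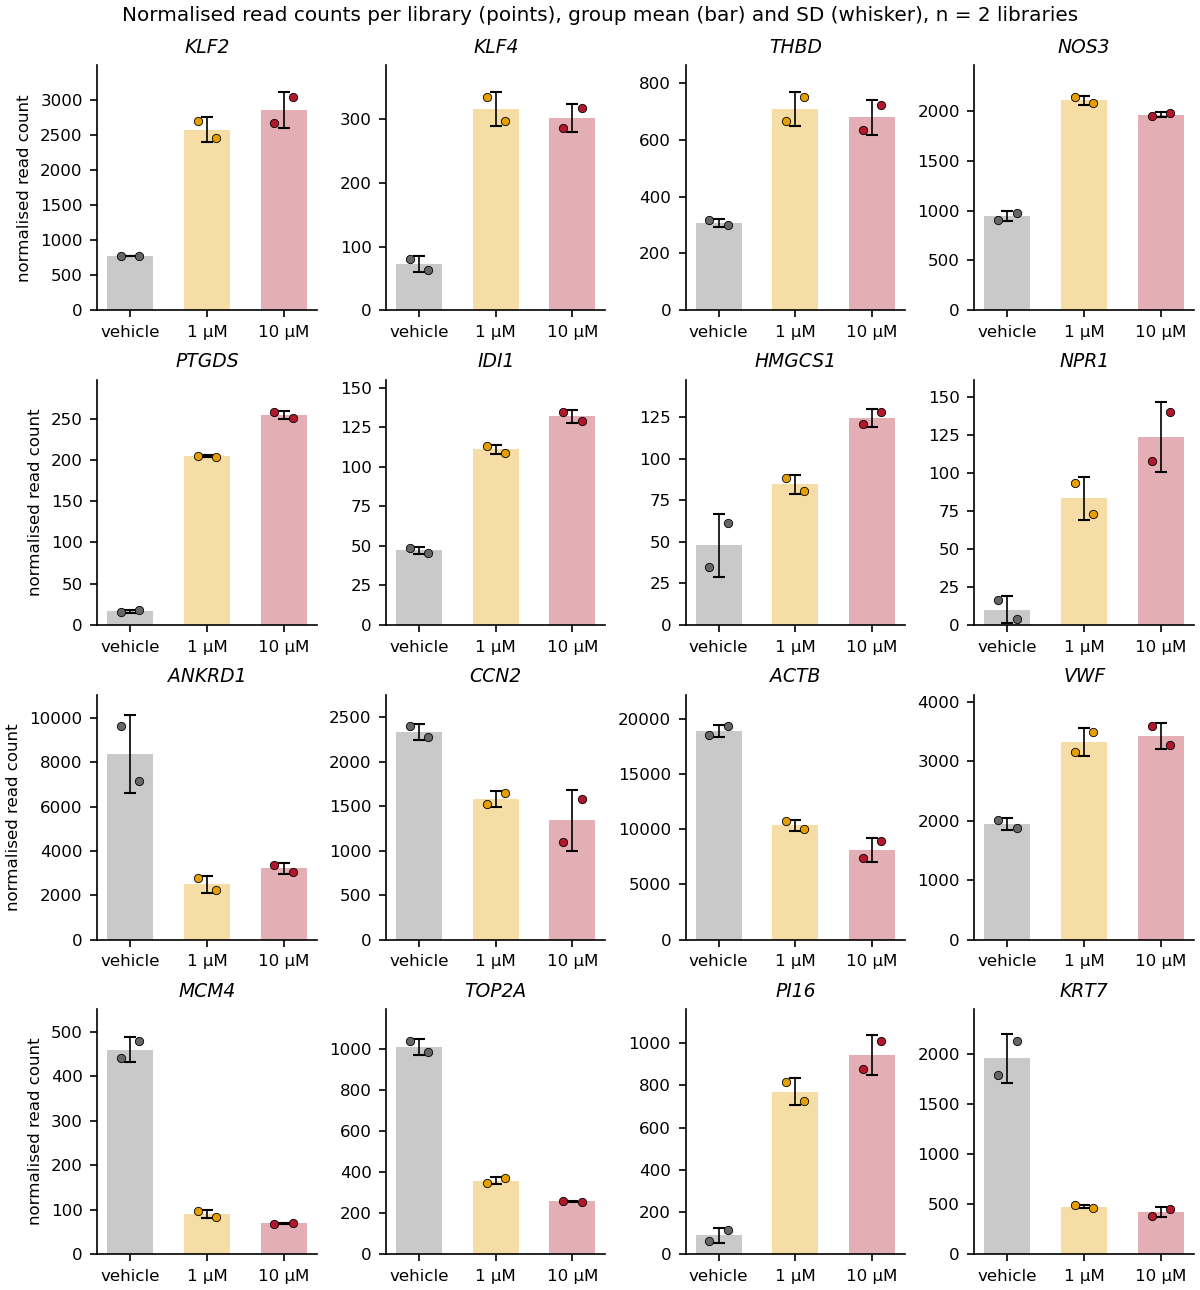
Normalised read count (linear axis from 0) of 16 genes in vehicle, 1 µM and 10 µM simvastatin, with bars for the mean, whiskers for the SD of 2 libraries and points for the libraries. KLF2 rose from 777 ± 1.98 in vehicle to 2579.7 ± 178 at 1 µM and 2859 ± 259 at 10 µM, while TOP2A fell from 1012 ± 39.0 to 358 ± 18.4 and 258 ± 2.26.

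With 10 µM simvastatin, KLF2, KLF4, PTGDS and HMGCS1 were higher than in vehicle, and TOP2A, MCM4 and ACTB were lower. KLF2 rose to 2859 ± 259 (SD, n = 2 libraries), a log2 fold change of 1.88 ± 0.13 (SE) over vehicle, KLF4 to 302 ± 21.6 (2.04 ± 0.20) and PTGDS to 255 ± 5.32 (3.80 ± 0.25). HMGCS1 rose from 48.0 ± 18.9 to 124 ± 5.34 (1.39 ± 0.28). TOP2A fell to 258 ± 2.26 (-1.96 ± 0.16), MCM4 to 69.5 ± 0.872 (-2.69 ± 0.22) and ACTB from 18921 ± 569 to 8140.5 ± 1082 (-1.22 ± 0.12).

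Over all genes, limma called 2554 of 14135 genes at an adjusted p of 0.05, 1331 higher and 1223 lower at 10 µM than in vehicle, of which 560 rose and 498 fell by more than 2-fold. NPR1 (3.58 ± 0.39) and the chemerin receptor CMKLR1 (3.33 ± 0.37) were among the named genes with the largest rises, although NPR1 was low and uneven in vehicle, with 4.39 without vehicle replicate 1 and 2.78 without vehicle replicate 2. PKMYT1, a kinase that holds back CDK1 (-3.03 ± 0.39), follistatin (FST, -2.76 ± 0.33) and NPPB (-2.66 ± 0.48) were among those with the largest falls, with PKMYT1 at -2.35 without 10 µM replicate 1 and -3.70 without 10 µM replicate 2. The edgeR test on the recovered reads called 2499 genes, of which 2417 were among those called by limma. Without 10 µM replicate 1 the limma count was 1506, and against a minimum fold of 1.5 it was 422.

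Of 23 cholesterol synthesis and SREBP2 target genes, 15 rose and 0 fell at 10 µM (17 and 0 adjusted over the list alone; median 0.93). For the cholesterol list at 10 µM, camera gave an adjusted p of 2.41e-07 (adjusted p = 0.113 with an estimated correlation). MSMO1 rose by 1.05 ± 0.16 and the regulator SREBF2 by 1.05 ± 0.17. Without vehicle replicate 1, 1 cholesterol gene fell. In the KLF2 or KLF4 list, 15 of 21 genes rose and 0 fell (17 and 0 adjusted over the list alone; median 1.06). For the KLF2 or KLF4 list at 10 µM, camera gave an adjusted p of 1.80e-10 (adjusted p = 0.152 with an estimated correlation). Examples were ELN at 2.12 ± 0.16, TEK at 1.89 ± 0.15 and NOS3 at 1.06 ± 0.13. Of 17 prostanoid, nitric oxide and vasoactive genes, 10 rose and 4 fell (10 and 4 adjusted over the list alone). For the vasoactive list at 10 µM, camera gave an adjusted p of 0.00924 (adjusted p = 0.196 with an estimated correlation). Prostacyclin synthase (PTGIS) rose by 2.10 ± 0.21, RAMP2 by 2.09 ± 0.16 and its partner CALCRL by 1.21 ± 0.14. Of 25 endothelial identity genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.37). For the identity list at 10 µM, camera gave an adjusted p of 0.00924 (adjusted p = 0.196 with an estimated correlation). PECAM1 rose by 0.64 ± 0.12 and PLVAP by 1.01 ± 0.21. Without vehicle replicate 1, 6 identity genes rose and the median was 0.30 with a camera adjusted p of 0.128, in a range of 0.00499 to 0.128 over 18 settings. Without 10 µM replicate 2, 5 identity genes rose and 2 vasoactive genes fell. The identity gene that fell lost its call when any 1 library other than 10 µM replicate 1 was left out and with no filter on low values.

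All 25 G2 and M phase genes tested fell at 10 µM (25 fell and 0 rose, also 25 adjusted over the list alone; median -2.00). For the G2 and M phase list at 10 µM, camera gave an adjusted p of 1.93e-26 (adjusted p = 0.0342 with an estimated correlation). Members that changed included TPX2 (-2.14 ± 0.17) and AURKB (-2.33 ± 0.23). Of 25 S phase genes, 21 fell and 0 rose (0 and 22 rose and fell adjusted over the list alone; median -1.61). For the S phase list at 10 µM, camera gave an adjusted p of 6.87e-18 (adjusted p = 0.113 with an estimated correlation). Members that changed included E2F1 (-2.43 ± 0.24), RRM2 (-2.43 ± 0.24) and the sliding clamp PCNA (-1.57 ± 0.17). Of 21 YAP and TAZ targets, 8 fell, 0 rose and 13 were not called (2 and 10 rose and fell adjusted over the list alone; median -0.37). For the YAP and TAZ list at 10 µM, camera gave an adjusted p of 0.00923 (adjusted p = 0.196 with an estimated correlation). Without vehicle replicate 2 or 10 µM replicate 2, 1 YAP and TAZ target rose. ANKRD1 had a log2 fold change of -1.37 ± 0.14, AXL of -0.79 ± 0.13, CCN1 of -0.91 ± 0.15 and CCN2 of -0.83 ± 0.14. Of 23 SRF and actin genes, 9 fell, 1 rose and 13 were not called (1 and 11 rose and fell adjusted over the list alone; median -0.55). For the SRF and actin list at 10 µM, camera gave an adjusted p of 2.80e-05 (adjusted p = 0.33 with an estimated correlation). Members that changed included ACTG1 (-0.97 ± 0.11), TPM1 (-1.08 ± 0.13) and FHL2 (-1.14 ± 0.14).

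Of 20 coagulation and fibrinolysis genes, 7 rose and 2 fell at 10 µM (8 and 4 adjusted over the list alone; camera adjusted p = 0.534). THBD rose to 679.5 ± 60.8 (1.13 ± 0.15), VWF rose by 0.82 ± 0.13, the plasminogen activator PLAT by 0.99 ± 0.15 and the ectonucleotidase ENTPD1 by 1.54 ± 0.27. At 10 µM, 4 coagulation genes fell without vehicle replicate 1, and 1 fell without vehicle replicate 2, without either 10 µM library or with no filter on low values. Of 20 immediate early genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.145), with FOSB at 1.44 ± 0.15 and NR4A2 at 1.44 ± 0.18. Of 14 heat shock genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.513), with HSPB1 at 0.89 ± 0.12 and HSPE1 at -1.26 ± 0.16. Without vehicle replicate 1, 2 heat shock and 0 immediate early genes fell, and without 10 µM replicate 1 or replicate 2, 1 immediate early gene fell, as with no filter on low values. The heat shock genes that rose were 1 without vehicle replicate 2 or 10 µM replicate 2, and 3 without vehicle replicate 1. Among markers of other cells at 10 µM, 2 of 7 fibroblast genes rose and 0 fell, 3 of 8 smooth muscle and pericyte genes fell and 0 rose, 0 of 3 leukocyte genes changed, 1 of 6 epithelial genes fell and 0 rose, and 1 of 6 lymphatic genes rose. Fibroblast genes that rose were 4 without vehicle replicate 1, and 1 without vehicle replicate 2 or with the GC and length trend removed, 1 smooth muscle gene fell without vehicle replicate 2 or 10 µM replicate 1, and the lymphatic gene was not called without vehicle replicate 2, 10 µM replicate 1 or 10 µM replicate 2. Without vehicle replicate 1, 1 smooth muscle gene rose, and with the GC and length trend removed 1 lymphatic gene fell. PI16 rose to 944 ± 94.7 (3.44 ± 0.20) and KRT7 fell to 419.8 ± 48.4 (-2.21 ± 0.15).

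**Figure D2:**
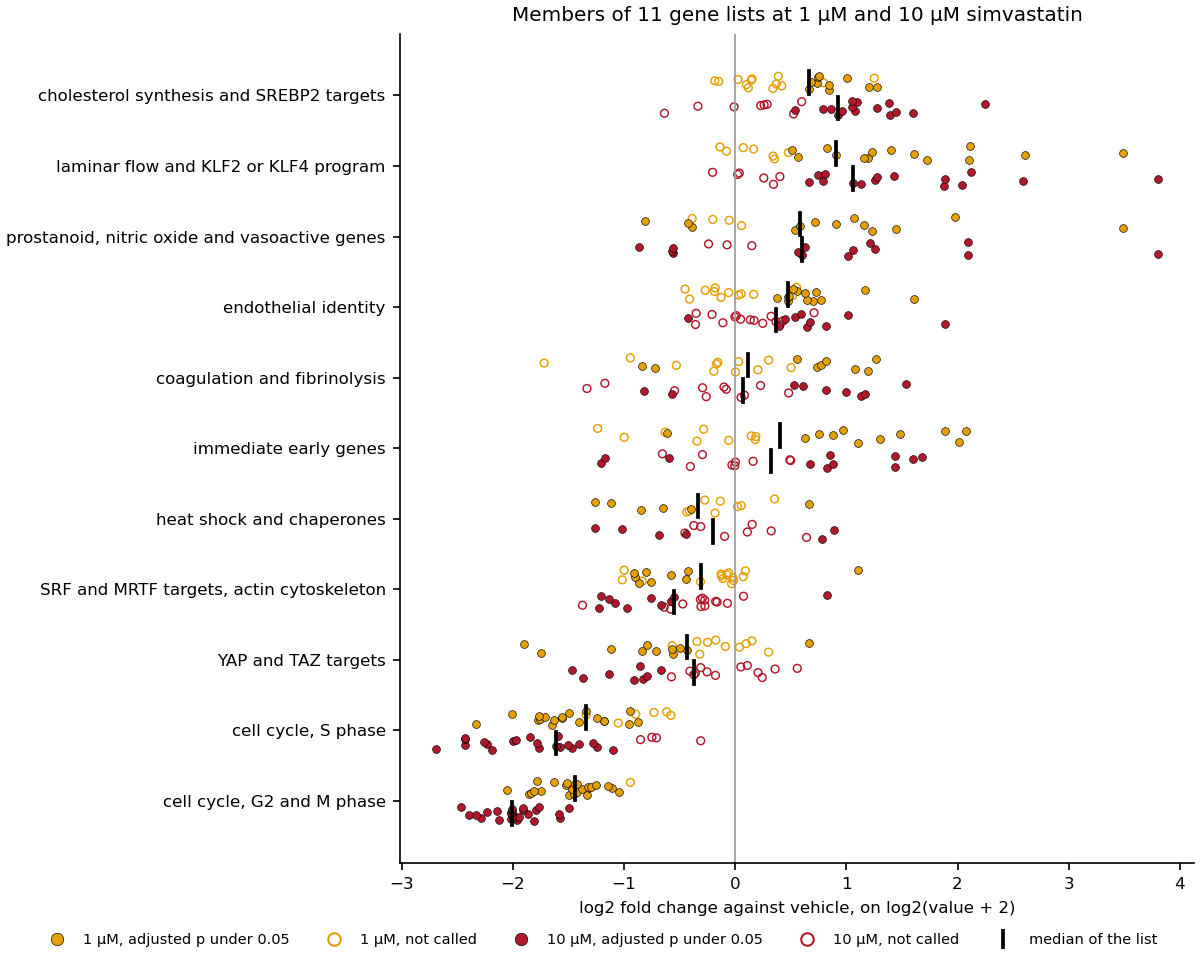
Log2 fold change against vehicle (x axis) of each tested member of 11 gene lists (y axis) at 1 µM and 10 µM simvastatin, with filled points for genes past an adjusted p of 0.05 and a black tick at the median of the list. The G2 and M phase list has medians of -1.44 and -2.00, and the KLF2 or KLF4 list of 0.91 and 1.06.

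Most genes called at 1 µM were called in the same direction at 10 µM. Of the 1029 genes higher at 1 µM, 835 were also higher at 10 µM (96.9 for independent lists), and of the 896 genes lower at 1 µM, 704 were also lower at 10 µM (77.5 for independent lists). No gene was called in opposite directions (0 genes). Across 14135 genes, which are not independent replicates, the log2 fold changes of the doses correlated at r = 0.845 (Spearman 0.805). Both comparisons use the same vehicle libraries. Unchanged libraries were simulated gene by gene, vehicle included, from 1 mean per gene over all 6 libraries. They gave a mean r of 0.577 (0.563 to 0.597 in 20 simulations), a mean Spearman correlation of 0.528 and 0.25 shared calls (0 to 2). The real vehicle libraries lay apart on the second principal component (41.0 and -30.8). Such draws carry no deviation shared across genes, so these values may understate what the shared controls produce. The covariance was 0.341, against 0.0732 in the simulations, an excess of 0.268. With 2 vehicle libraries the controls could not be split into parts of at least 2 libraries, so part of the excess in overlap may come from the shared controls.

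**Figure D3:**
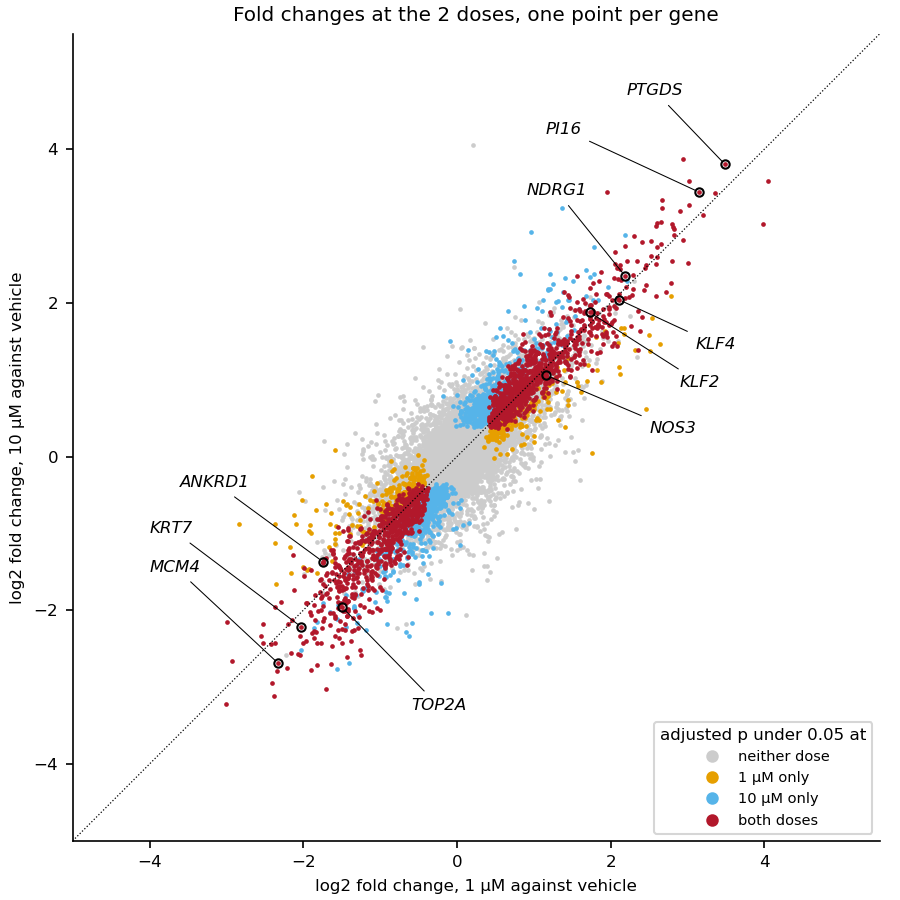
Log2 fold change against vehicle at 1 µM (x axis) and at 10 µM (y axis) for each of the 14135 genes tested, coloured by call, with 10 genes named. PTGDS lies at 3.49 and 3.80 and MCM4 at -2.33 and -2.69, and r over all genes is 0.845.

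Between the doses, no single gene passed, while some lists ranked higher or lower at 10 µM. The median of the G2 and M phase genes was lower at 10 µM than at 1 µM by a log2 difference of -0.47 (camera adjusted p = 5.34e-15, adjusted p = 0.0795 with an estimated correlation). Over all genes 0 of 25 members passed and 14 passed as lower adjusted over the list alone. The cholesterol synthesis list had a median difference of 0.26 (0 of 23 members passed; camera adjusted p = 1.83e-04, adjusted p = 0.283 with an estimated correlation) and the S phase list of -0.37 (0 of 25; camera adjusted p = 8.26e-05, adjusted p = 0.651 with an estimated correlation). Adjusted over the list alone, 1 cholesterol gene passed as higher, and 2 S phase genes, 0 SRF genes and 2 immediate early genes passed as lower. Between the doses the directional fry test called only the G2 and M phase list (fry adjusted p = 0.0254). Its adjusted p was 0.218 for the cholesterol, 0.286 for the S phase, 0.357 for the SRF and 0.371 for the immediate early list. The S phase median was -0.22 without 10 µM replicate 1 and -0.23 in thinned libraries. The SRF and actin list had a median difference of -0.21 (camera adjusted p = 0.0118, adjusted p = 0.661 with an estimated correlation), a call lost without 1 µM replicate 2 (-0.17) or 10 µM replicate 1 (-0.10) and with no filter on low values (-0.21, adjusted p = 0.0585), in a range of 0.00251 to 0.186 over 18 settings. The immediate early list had -0.19 (camera adjusted p = 0.0363, adjusted p = 0.659 with an estimated correlation), a call lost without vehicle replicate 1 (-0.19), vehicle replicate 2 (-0.19), 1 µM replicate 2 (-0.17) or 10 µM replicate 1 (-0.05). It was also lost in thinned libraries (-0.16, adjusted p = 0.0861), with the GC and length trend removed (-0.15, adjusted p = 0.106) and with no filter on low values (-0.15, adjusted p = 0.195), and it passed in 11 of 18 settings (0.00578 to 0.319).

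At an adjusted p of 0.05, limma called 0 of 14135 genes between 10 µM and 1 µM, with 841 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.322. edgeR on the recovered reads called 0 of 14300 genes (1001 at an unadjusted p under 0.05) and DESeq2 called 0 of 27638 (552). Without any change, a share of 0.05 of the genes tested would fall under that unadjusted threshold. These counts are therefore not counts of genes that differ between the doses. A missed threshold does not show that the doses acted alike, and the 95% interval of the difference reached a median of 0.53 on the log2 scale to either side. It ran from -0.12 to 0.42 for KLF2, from -0.47 to 0.34 for KLF4, from -0.37 to 0.25 for THBD, from -0.37 to 0.17 for NOS3, from -0.02 to 1.12 for HMGCS1 and from -0.56 to 0.03 for CCN2. CCN1 had a difference of -0.59 ± 0.15 (interval -0.89 to -0.29; limma adjusted p = 0.602). Other differences with small unadjusted p were those of the mitotic genes KIF20A (-0.94 ± 0.23) and BUB1 (-0.93 ± 0.30), of FOSB (-0.58 ± 0.15) and ACTB (-0.35 ± 0.12), and of FDPS (0.66 ± 0.20), which makes farnesyl diphosphate. The chaperone HSPA1A, whose reads cannot be separated with certainty from those of its near-identical copy HSPA1B, had 0.96 ± 0.20 (limma adjusted p = 0.322).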

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

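The thinned libraries and the GC and length correction were chosen only after the data were seen. The differences between the doses below drew attention because camera passed for the list while 0 single genes passed with limma, edgeR or DESeq2. With limma, 841 of 14135 genes had an unadjusted p under 0.05, where a share of 0.05 would pass without any change. The directional fry test passed only for the G2 and M phase list (fry adjusted p = 0.0254). The mixed fry test, which leaves the direction of each gene open, passed for 3 lists. These were the G2 and M phase (mixed fry adjusted p = 7.08e-04), cholesterol (0.00511) and vasoactive (0.00511) lists.

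G2 and M phase genes had a median log2 fold change of -0.474 at 10 µM against 1 µM, with a camera adjusted p of 5.34e-15 (adjusted p = 0.0795 with an estimated correlation). A difference in depth between the dose groups is argued against by libraries thinned to the depth of the shallowest, where the median was -0.594. A single library is argued against by leaving out each treated library, where the highest median was -0.473, and a GC or length bias by the corrected values, where the median was -0.539. Whether the higher dose lowered the share of dividing cells further was not tested here. Whether the libraries of a dose were handled together, and the density of the cultures, are not given in the sources used here and stay open.

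The median difference at 10 µM against 1 µM was -0.37 for the S phase list (adjusted p = 0.651 with an estimated correlation), and -0.22 without 10 µM replicate 1 and -0.23 in thinned libraries. It was 0.261 for the cholesterol synthesis list (adjusted p = 0.283 with an estimated correlation). It was -0.214 for the SRF and actin list (adjusted p = 0.661 with an estimated correlation), and its camera call was lost without 1 µM replicate 2 (-0.17) or 10 µM replicate 1 (-0.10) and with no filter on low values (-0.21, adjusted p = 0.0585), in a range of 0.00251 to 0.186 over 18 settings. It was -0.194 for the immediate early list (adjusted p = 0.659 with an estimated correlation), and its call was lost without vehicle replicate 1 (-0.19), vehicle replicate 2 (-0.19), 1 µM replicate 2 (-0.17) or 10 µM replicate 1 (-0.05). It was also lost in thinned libraries (-0.16, adjusted p = 0.0861), with the GC and length trend removed (-0.15, adjusted p = 0.106) and with no filter on low values (-0.15, adjusted p = 0.195), and it passed in 11 of 18 settings (0.00578 to 0.319).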

How the results depend on the processing

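The test planned in the design was edgeR with TMM on raw counts. Limma on log2(value + 2) replaced it as the main test only after the deposited unit was seen. The planned edgeR test was then run on the recovered reads. Pseudocounts of 0.5 and 10, TMM scaling, a total without mitochondrial genes, thinned libraries and the GC and length correction were also chosen only after the data were seen. A gene's direction did not reverse in any alternative run (0 of the results for lists and named genes that were called), and no alternative called a gene in the direction opposite to its first call (0 genes). The counts of called genes at 1 µM and 10 µM were 1925 and 2554. They were 1593 and 2152 in thinned libraries, 1400 and 1860 with DESeq2, and 1605 and 2209 with no filter on low values. They were 1125 and 1563 at an adjusted p of 0.01, and 248 and 422 against a minimum fold of 1.5, settings that are stricter by construction. Leaving out each library in turn gave 924 to 1965 genes at 1 µM, 1506 to 2623 at 10 µM and 0 to 3 between the doses. Where this left a group with 1 library, it was assumed to vary like the other groups. Similar totals did not mean the same genes, as without vehicle replicate 1 part of the calls were replaced by others. Of 117 calls of named genes, 45 were lost against the minimum fold, and 114 were kept in every other alternative run for single genes. The remaining 3 belong to HMGCS1 and CCN2 at 1 µM and to COL1A1 at 10 µM. Named genes outside the fixed set were mostly picked for large changes or small adjusted p in these data. Their stability therefore does not stand for that of all genes. Over all genes, DESeq2 called 1387 of the 1925 genes again at 1 µM and 1843 of the 2554 at 10 µM.

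Between the doses, edgeR without robust estimation called 4 genes (NCAPG2, HSPA1A, LINC01643 and NEAT1) and limma-voom called 1 (HSPA1A). Without 1 µM replicate 1, 2 genes passed (IGF2 and THORLNC), without 1 µM replicate 2, 3 passed (NCAPG2, LINC02643 and NEAT1), and without 10 µM replicate 2, 2 passed (ST3GAL6 and NEAT1). Apart from HSPA1A these genes were named after their values were seen, and the cause was not tested. Among lists not called, the NF-kB list at 1 µM passed camera in 5 of 18 settings (adjusted p 0.028 to 0.209), the fibroblast list at 1 µM in 3 (0.0269 to 0.293), and in 1 each the immediate early list at 10 µM (0.0387, without 10 µM replicate 1), the integrated stress response list at 10 µM (0.0193, no filter on low values), and between the doses the heat shock list (0.0285, GC and length trend removed) and the leukocyte list (0.0181, without 1 µM replicate 1). A pseudocount of 10 gave smaller log2 fold changes for low genes, of 2.73 for SMTNL2 at 1 µM, 2.28 and 2.80 for NPR1 and -2.20 and -2.05 for NPPB at 1 µM and 10 µM, and 2.63 for CMKLR1 at 10 µM, while edgeR with TMM gave 4.68 and DESeq2 4.73 for SMTNL2. The correlation of the dose effects was 0.805 as a Spearman correlation and 0.881 over 11664 genes with at least 5 CPM.

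Replicate numbers are shared between the groups, but the labels do not say that they pair the libraries. The deviations of same-numbered libraries correlated at -0.02, 0.079 and -0.11. With the replicate number as a block, limma called 1943, 2564 and 0 genes. Without mitochondrial genes, ribosomal protein genes took 4.31% to 5.33% and the 20 most abundant genes 7.55% to 8.04% of a library's reads. Depth limits low genes most in the vehicle libraries, the shallowest of which had 2370581 reads.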

Other observations

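The tests for fibroblasts, for epithelial cells and for p53 targets, the thinned libraries and the GC and length correction were chosen only after the results were seen. Among genes that respond to inflammation, ICAM1, a leukocyte adhesion molecule, rose by 1.64 ± 0.28 (log2 fold change ± SE, n = 2 libraries per group) at 1 µM and 1.66 ± 0.28 at 10 µM, and NFKBIA, the inhibitor of NF-kB, by 1.05 ± 0.18 and 1.02 ± 0.18. Of 16 NF-kB targets, 6 rose and 1 fell at 1 µM and 5 rose and 1 fell at 10 µM (6 and 1, and 6 and 1, adjusted over the list alone; camera adjusted p = 0.0569 and 0.319). Of 20 interferon genes, 3 rose and 0 fell at 1 µM and 3 rose and 1 fell at 10 µM (3 and 0, and 3 and 1, adjusted over the list alone; camera adjusted p = 0.148 and 0.513). Among angiogenic genes, ANGPT2, an antagonist of TEK, had -0.90 ± 0.17 and -0.82 ± 0.17, and the peptide APLN -0.87 ± 0.17 and -1.37 ± 0.17. Of 22 genes of that list, 5 rose and 5 fell at 1 µM and 5 rose and 6 fell at 10 µM (6 and 7, and 6 and 7, adjusted over the list alone; camera adjusted p = 0.832 and 0.513). BMPER, a BMP binding protein, rose by 1.66 ± 0.16 and 1.87 ± 0.16 and ID1 by 1.41 ± 0.14 and 1.37 ± 0.14, while BMP4 had -0.86 ± 0.15 and -0.89 ± 0.15. Of 19 BMP and ID genes, 4 rose and 2 fell at 1 µM and 4 rose and 2 fell at 10 µM (4 and 2, and 5 and 3, adjusted over the list alone; camera adjusted p = 0.832 and 0.513). Of 23 endothelial to mesenchymal transition genes, 2 rose and 4 fell at 1 µM and 2 rose and 5 fell at 10 µM (3 and 7, and 3 and 6, adjusted over the list alone; camera adjusted p = 0.353 and 0.16), with N-cadherin (CDH2) at -1.01 ± 0.17 and -1.04 ± 0.17.

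Stress and metabolic genes went in both directions. The serine synthesis enzyme PSAT1 had log2 fold changes of -1.17 ± 0.28 at 1 µM and -1.66 ± 0.28 at 10 µM and STC2 of -1.35 ± 0.20 and -1.66 ± 0.20, while ATF3 rose by 0.97 ± 0.18 and 0.85 ± 0.18. Of 23 integrated stress response genes, 1 rose and 4 fell at 1 µM and 1 rose and 6 fell at 10 µM (1 and 6, and 1 and 8, adjusted over the list alone; camera adjusted p = 0.249 and 0.115), and the chaperone HSPA5 had -0.71 ± 0.13 at 10 µM. NDRG1 rose by 2.19 ± 0.16 and 2.35 ± 0.16 and the growth factor VEGFA by 1.43 ± 0.26 and 1.48 ± 0.26, while the glycolytic enzyme ENO1 had -0.83 ± 0.13 at 10 µM. Of 18 hypoxia and glycolysis genes, 2 rose and 2 fell at 1 µM and 3 rose and 6 fell at 10 µM (3 and 2, and 3 and 7, adjusted over the list alone; camera adjusted p = 0.832 and 0.313). Of 15 oxidative stress genes, 3 rose and 2 fell at 1 µM and 3 rose and 1 fell at 10 µM (5 and 3, and 3 and 1, adjusted over the list alone; camera adjusted p = 0.832 and 0.769), with the heme oxygenase HMOX1 at 0.79 ± 0.15 at 10 µM. Few genes were called in the fatty acid list (1 of 11 rose at each dose, ACSS2 at 1.35 ± 0.22 at 10 µM; camera adjusted p = 0.763 and 0.561), the LXR list (of 11, 1 rose and 0 fell at 1 µM and 1 rose and 1 fell at 10 µM; 0.832 and 0.769) and the apoptosis list (of 15, 2 rose and 1 fell at 1 µM and 1 rose and 0 fell at 10 µM; 0.832 and 0.769), with as many calls adjusted over the list alone. Camera called none of the 5 lists of other-cell markers at either dose, with adjusted p at 1 µM and 10 µM of 0.0575 and 0.207 for fibroblasts, 0.134 and 0.114 for smooth muscle, 0.478 and 0.769 for leukocytes, 0.869 and 0.769 for epithelial and red cells and 0.754 and 0.769 for lymphatic cells. Adjusted over the list alone, 4 and 3 fibroblast genes rose and 2 and 3 smooth muscle genes fell. With each library left out in turn, the fewest that rose and fell at 1 µM were 3 and 0 for NF-kB, 0 and 0 for interferon, 2 and 2 for angiogenesis, 3 and 1 for BMP and ID, 0 and 1 for the mesenchymal transition, 1 and 3 for the integrated stress response, 2 and 0 for hypoxia, 1 and 0 for oxidative stress, 0 and 0 for fatty acids, 0 and 0 for LXR and 1 and 0 for apoptosis. At 10 µM the fewest were 3 and 0 for NF-kB, 1 and 1 for interferon, 2 and 3 for angiogenesis, 3 and 1 for BMP and ID, 0 and 3 for the mesenchymal transition, 1 and 5 for the integrated stress response, 2 and 3 for hypoxia, 3 and 0 for oxidative stress, 1 and 0 for fatty acids, 0 and 0 for LXR and 0 and 0 for apoptosis. In the fatty acid list 1 gene fell at 1 µM without vehicle replicate 1, and 1 at 10 µM with the GC and length trend removed. The median, the mean and the camera direction did not all share a sign for the fatty acid, angiogenesis, BMP, p53, hypoxia, apoptosis and epithelial lists at 1 µM and for the apoptosis and epithelial lists at 10 µM.

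The 50 S and G2 and M phase genes had a median log2 fold change of -1.93 at 10 µM against vehicle, with 46 lower, and of -1.42 at 1 µM, with 43 lower. The shallowest library was a vehicle library, but lower depth is argued against by the thinned libraries, where the median at 10 µM was also -1.93. A single aberrant vehicle library is argued against by leaving out each in turn, where the highest median was -1.89. Whether simvastatin slowed the cell cycle was not tested here. Culture density and handling at harvest are not given in the sources used here and stay open.

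A hypothesis for the lower cell cycle genes was an induction of p53 targets, which would raise CDKN1A and MDM2. At 10 µM CDKN1A had a log2 fold change of -0.15 ± 0.132 and MDM2 of -0.03 ± 0.145. The higher of their upper 95% bounds was 0.262, below a rise of 0.5. Both genes and the bound of 0.5 were chosen after these values were seen, so this was not a prediction that could have failed. The list of p53 targets also holds genes of cell cycle arrest (CDKN1B, CDKN2B and CDKN1C), so it is not of p53 targets alone. Of its 20 genes, 1 rose and 1 fell at each dose, also adjusted over the list alone (camera adjusted p = 0.832 at 1 µM and 0.608 at 10 µM). The fall was not stable when a library was left out, and 2 genes fell at 10 µM with the GC and length trend removed. The target that rose was BTG2 (log2 fold change 0.93 at 1 µM and 0.65 at 10 µM), and GDF15 fell (-0.48 and -0.53). The intervals of CDKN1A and MDM2 argue against a rise of 0.5 in these transcripts at 10 µM.

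PI16 rose and KRT7 fell at both doses, although PI16 is on the fibroblast list and KRT7 on the epithelial list. Of the 11 genes of the fibroblast list, 7 passed the filter on low values and were tested. Fibroblasts in the treated cultures are argued against, as far as a single transcript can, by DCN, an abundant fibroblast transcript named after its values were seen. Its log2 fold change at 10 µM had an upper 95% bound of 0.443, at levels of 25.8 in vehicle and 19.1 at 10 µM. COL1A1 went the other way, from 4946 in vehicle to 6908 at 10 µM (log2 fold change 0.47), a call lost without vehicle replicate 2 (0.46) and with the GC and length trend removed (0.25), and COL1A2 (0.37, 95% interval 0.07 to 0.67), COL3A1 (0.09) and LSP1 (1.54, limma adjusted p = 0.165; near the counting floor) were also above 0 without passing. For epithelial cells in the vehicle cultures, KRT8, KRT18 and KRT19 were chosen after the results were seen, so this was not a prediction that could have failed. Their log2 fold changes at 10 µM were 0.27, 0.11 and 0.49, with a lowest lower 95% bound of -0.317. Their levels in vehicle were 215, 217 and 179, against 1957 for KRT7. Which cells made these transcripts was not tested. Steady levels could therefore hide a loss of epithelial cells and do not decide the question. Depth or a single library is argued against by an adjusted p (limma) of at most 1.62e-06 for either PI16 or KRT7 over thinning and the leave-outs. A response of the endothelial cells themselves was not tested. A mixture with epithelial cells, or with cells that lack the markers named here, stays open.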
